A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

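Total RNA was taken from budding yeast (Saccharomyces cerevisiae) grown in YPD, a rich glucose medium, at 30 °C and harvested at an OD600 of 1.0, per the labels' protocols. Libraries were made with a directional kit, which marks the strand of the RNA, and sequenced on an Illumina HiSeq instrument. There were 2 groups of 2 libraries: wild type (WT) and a strain whose Swd2 protein carries a tag of 9 Myc epitopes at its N terminus (9Myc-Swd2). The groups and replicate numbers were taken from the labels.

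The authors deposited 1 table of 6697 genes. Its 4 library columns hold a signal that the authors made by dividing read counts by 1 size factor per library. The division was found from the values: in each column 100% of the values were whole multiples of 1 step, to within 1e-06 steps. The steps were 0.950, 0.972, 1.06 and 1.01 for WT 1, WT 2, 9Myc-Swd2 1 and 9Myc-Swd2 2. The median-of-ratios size factors of the whole reads recovered in this way equalled the inverse steps, which gave 1.05, 1.03, 0.940 and 0.992. The deposited table also holds the authors' own comparison, with log2 fold changes and their standard errors, a score (the Wald statistic), p-values and adjusted p-values, per the file headers. 2 further deposited columns hold the log10 of each group's mean value and were not used. The log2 fold changes that DESeq2 gave here on the recovered reads differed from the deposited ones by at most 5.23e-05. Per the submitters' processing notes the reads were demultiplexed with bcl2fastq 1.8.4 and the genome build was sacCer3. The aligner, the read counter and whether counting used the strand are not given in the sources used here. Reads of overlapping genes, antisense genes and near-identical paralogs could therefore not be told apart.

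The recovered reads summed to 8388090 and 8327878 in the WT libraries and to 7849193 and 8316221 in the 9Myc-Swd2 libraries. Between 6488 and 6515 genes had at least 1 read in a library, and 163 had none in any. The chi-square per gene between the recovered reads was 3.42 for the WT pair and 8.84 for the 9Myc-Swd2 pair, so that no library repeated another within sampling noise.

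The design written before the data were examined foresaw counts or values such as CPM. Because the columns hold normalized values, the test set for such values was used: limma-trend on log2(value + 1), with the group as the only term, on the 6503 genes with a mean value of at least 1 over the 4 libraries. All p-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. A fold change is on the log2(value + 1) scale, which understates the change of genes with low values. Errors of values are SDs over the 2 libraries of a group, and errors of log2 fold changes are standard errors (SE). Gene lists were tested with camera at a preset correlation of 0.01 between genes, against all other genes. Camera with an estimated correlation, given beside it, rests on 2 residual degrees of freedom. A failure to pass there is weak evidence against a list. 46 lists were fixed before the data were examined, 43 had members in the table, and all 43 were tested. The table held no member of the lists of snoRNA genes, of Ty and LTR elements and of ribosomal RNA. Named genes followed a rule fixed at the same time. They were SWD2, the 10 largest rises and 10 largest falls past the threshold in which both tagged libraries lay on the same side of both WT libraries with a mean of at least 5 CPM, at most 4 members with the smallest p per list, and the members past the threshold among COMPASS and CPF/APT subunits, selectable markers and the 3 neighbours of SWD2 on each side. Any other gene is said to have been chosen after its values were seen. The comparison of chromosomes, 3 further lists and the related tests were also chosen after the values were seen.

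Chromosome and gene positions came from the RefSeq annotation of the R64 assembly of strain S288C, which is the assembly that sacCer3 names; the table itself holds no positions. 6014 of the 6697 identifiers (89.8%) matched a RefSeq locus tag. For the others the chromosome was read from the systematic name, which gave the RefSeq chromosome in 100% of the matched genes. Positions are 1-based. Chromosome medians were taken over genes with a mean of at least 5 CPM, and windows along chromosomes held at least 25 such genes. The trend on GC content and gene length was removed with a loess curve of span 0.5.

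Alternatives listed before the data were examined were quantile normalization, no filter, a filter at 5 CPM, limma without a trend, a replicate block, a pseudocount of 0.1, each library left out in turn, the authors' deposited comparison at 0.05 and 0.01, a minimum log2 fold change of 1, camera with an estimated correlation, and fry. Alternatives added afterwards were edgeR's quasi-likelihood test and DESeq2 on the recovered reads, the tests without chromosome XI genes, scaling to total counts, and size factors without chromosome XI genes. With 2 libraries per group a regrouping of the samples was not used as a test.

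The code was tested on simulated data, in which the changed genes were drawn only from those of at least 5 CPM and all others were unchanged. The simulated spread followed a trend with expression level, the same in both groups, without variation of single genes about it. For the comparison of 9Myc-Swd2 with WT, simulated over 6496 genes, limma-trend recovered 100% of 100 genes changed 2-fold and 93% of 100 genes changed 1.5-fold, with 5 false calls. edgeR recovered 100% and 93% with 7 false calls over 6273 genes, and DESeq2 97% and 82% with 2 false calls over 6532 genes. Calculations were made with R 4.3.3, limma 3.58.1, edgeR 4.0.16, DESeq2 1.42.0, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.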

Results

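mRNA abundance was measured by RNA sequencing in a budding yeast strain that expresses Swd2 with an N-terminal tag of 9 Myc epitopes and in a wild type that the design text calls isogenic, with 2 libraries of each. Swd2 is a WD-repeat protein shared by COMPASS, the complex in which Set1 methylates lysine 4 of histone H3, and by the cleavage and polyadenylation factor (CPF), in its APT module. The comparison asked how gene expression differed between the strain with the tag and the strain without it. The WT libraries held 8388090 and 8327878 reads assigned to genes, and the 9Myc-Swd2 libraries 7849193 and 8316221. Values are the authors' normalized read counts, and fold changes are those of 9Myc-Swd2 over WT. The labels do not say that the libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. Pearson's r of log values across genes was 0.995 between the WT libraries and 0.992 between the 9Myc-Swd2 libraries; genes are not independent replicates.

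SWD2 itself (YKL018W, R64 chromosome XI, 404102 to 405091, plus strand, 1 exon) was read at 335 and 351 normalized counts in the WT libraries and at 1080 and 969 in the 9Myc-Swd2 libraries. Its mean rose from 343 ± 11.5 to 1025 ± 78.9 (SD, n = 2 each), a log2 fold change of 1.58 ± 0.08 (SE) with a limma-trend adjusted p of 2.4e-10. The authors' deposited table gives 1.58 with an adjusted p of 1.73e-34. All 6 nearest annotated genes rose too: SPT23, RAM2 and YKL018C-A on the lower-coordinate side, and HCS1, ATP7 and PUT3 on the other side. Their log2 fold changes lay between 0.80 (RAM2, a farnesyltransferase subunit) and 1.65 (PUT3, the activator of proline utilization genes). As a list these neighbours passed the camera test (adjusted p = 8e-07, and 0.77 with an estimated correlation), and all 6 passed when adjusted over the list alone. That test compared them with genes of all chromosomes. On chromosome XI as a whole 90.6% of the tested genes rose, so the pass does not point to an effect near SWD2. The median log2 fold change was 1.00 for the neighbours and 0.90 for chromosome XI genes of at least 5 CPM.

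Genes of chromosome XI were higher in 9Myc-Swd2 as a whole. Of its 342 tested genes, 310 rose (90.6%), 2 fell and 30 did not pass the threshold, whereas 1138 of the 6161 genes elsewhere rose (18.5%) and 1391 fell. The median log2 fold change over its 319 genes of at least 5 CPM was 0.90 (interquartile range 0.70 to 1.11), which is 1.87-fold, and 98.1% of them lay above 0. The other nuclear chromosomes had medians between -0.06 (chromosome VII) and 0.06 (chromosome III). The increase was seen in both tagged libraries: the median difference on chromosome XI was 0.94 and 0.93 for 9Myc-Swd2 1 over the WT libraries and 0.89 and 0.90 for 9Myc-Swd2 2, against 0.02 between the WT libraries and 0.05 between the tagged ones. Reads of chromosome XI made up 5.79% ± 0.0127 of the WT libraries and 9.54% ± 0.177 of the 9Myc-Swd2 libraries (SD, n = 2). The partition by chromosome was chosen after the values were seen. Among the 17 chromosomes, the mitochondrial one included, the camera adjusted p of chromosome XI was 1.08e-71; it was 0.20 with an estimated correlation, which rests on 2 residual degrees of freedom.

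**Figure D1:**
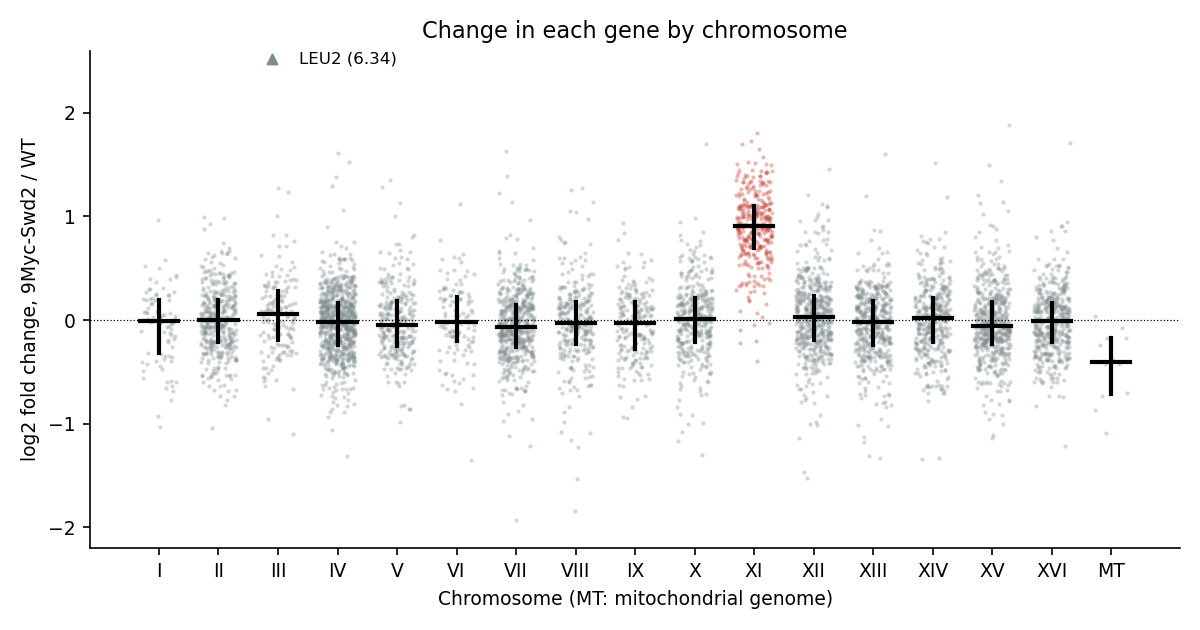
Log2 fold change of 9Myc-Swd2 over WT (y axis) of each gene with a mean of at least 5 CPM, by chromosome (x axis; MT is the mitochondrial genome); horizontal bars are medians, vertical bars interquartile ranges, and the triangle marks LEU2, which lies outside the axis at 6.34. Chromosome XI has a median of 0.90, and the other nuclear chromosomes lie between -0.06 and 0.06.

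The rise extended along the whole of chromosome XI. The left arm had a median log2 fold change of 0.91 over 218 genes and the right arm 0.89 over 101 genes. The 12 consecutive windows of at least 25 genes had medians from 0.82 to 0.99, and the 209 windows on other nuclear chromosomes from -0.21 to 0.20. SWD2 exceeded the chromosome XI median by 0.67 on the log2 scale, and 4 of the 318 other chromosome XI genes exceeded SWD2. Only TVP38 (-0.40 ± 0.09) and OAC1 (-0.22 ± 0.08), a mitochondrial oxaloacetate and isopropylmalate carrier, passed the threshold with a fall on this chromosome; STE3, the a-factor receptor of alpha cells, was at 1919.7 ± 59.0 in WT and 1802 ± 81.9 in 9Myc-Swd2. OAC1 did not pass the threshold in the authors' deposited table (adjusted p = 0.12) or with either WT library left out (limma adjusted p = 0.20 without WT 1 and 0.087 without WT 2). These 3 genes were chosen after their values were seen.

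**Figure D2:**
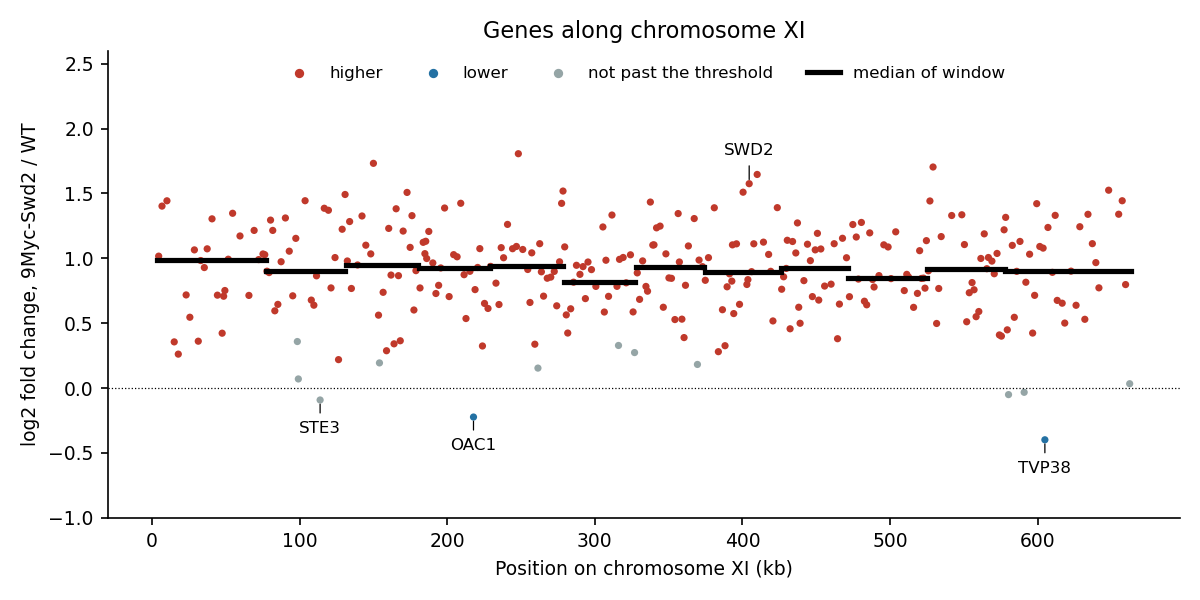
Log2 fold change of 9Myc-Swd2 over WT (y axis) of genes with a mean of at least 5 CPM against their position on chromosome XI in kb (x axis, R64); red, blue and grey points are genes that were higher, lower or not past the threshold, and black bars are medians of windows of at least 25 genes. The window medians lie between 0.82 and 0.99 along the chromosome, and SWD2 lies at 1.58.

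Over all 6503 genes tested, 1448 were higher and 1393 lower in 9Myc-Swd2 at a limma-trend adjusted p under 0.05, and 3662 did not pass. At least 2-fold changes were fewer, with 182 genes higher, 130 of them on chromosome XI, and 52 lower. In 71.6% of the genes both tagged libraries lay above or below both WT libraries, where chance gives 33.3%. The authors' deposited table has 1094 genes higher and 955 lower at 0.05 among 6154 genes with an adjusted p, and 2045 of these 2049 calls were also made here with the same sign. edgeR's quasi-likelihood test on the recovered reads called 1500 higher and 1399 lower. Higher genes made up 51.0% of the calls, but 40.9% when libraries were scaled to their total counts (1196 higher, 1728 lower). The number of lower genes was 780 without WT replicate 2 and 882 with limma without a trend.

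The largest rise was that of LEU2 (YCL018W, chromosome III, 91324 to 92418, plus strand), which encodes the isopropylmalate dehydrogenase of leucine synthesis. It was at 31.4 and 22.4 normalized counts in the WT libraries and at 2276 and 2163 in the 9Myc-Swd2 libraries, a log2 fold change of 6.34 ± 0.14 (SE, limma-trend adjusted p = 1.07e-15). Its neighbour NFS1, a cysteine desulfurase chosen after its value was seen, rose from 927 ± 82.0 to 1570 ± 0.0680. The other rises among the top 10 lay between log2 fold changes of 1.61 and 1.88. KDX1, TRK2 (a potassium transporter), PUT3 and the reading frame YKL102C are on chromosome XI. FIT3, a cell wall mannoprotein that retains siderophore-bound iron, rose from 1311 ± 41.2 to 4854 ± 720. ZPR1, a zinc finger protein needed for folding of translation elongation factor 1A, rose from 2252 ± 18.7 to 7015 ± 787. ATG41, which acts in autophagy, rose from 565 ± 13.5 to 1862 ± 217, and the little-characterized YJL047C-A and YDR042C completed the group.

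Among the 10 largest falls, none of them on chromosome XI, were LEU1 and BAT1, both enzymes of branched-chain amino acid synthesis. LEU1 (chromosome VII, 476313 to 478652, minus strand), the isopropylmalate isomerase, fell from 2836 ± 10.3 to 744 ± 54.6, a log2 fold change of -1.93 ± 0.07 (limma-trend adjusted p = 5.6e-12). BAT1 (chromosome VIII, 517532 to 518713, plus strand), the mitochondrial branched-chain aminotransferase, fell from 3027 ± 12.6 to 1050 ± 122 (-1.53 ± 0.08). BNA5, BNA6 and BNA7, which act in the synthesis of NAD from tryptophan, had log2 fold changes of -1.52, -1.35 and -1.32. PCL1, a G1 cyclin, fell from 446 ± 7.75 to 176 ± 20.4, and FMS1, a polyamine oxidase, from 737 ± 36.6 to 293 ± 12.4. COS8, YNL040W and YLR198C completed the group, with log2 fold changes of -1.84, -1.33 and -1.47. YLR198C had no RefSeq record, and whether it overlaps another gene was not tested; COS8 belongs to a multigene family whose reads may be shared.

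**Figure D3:**
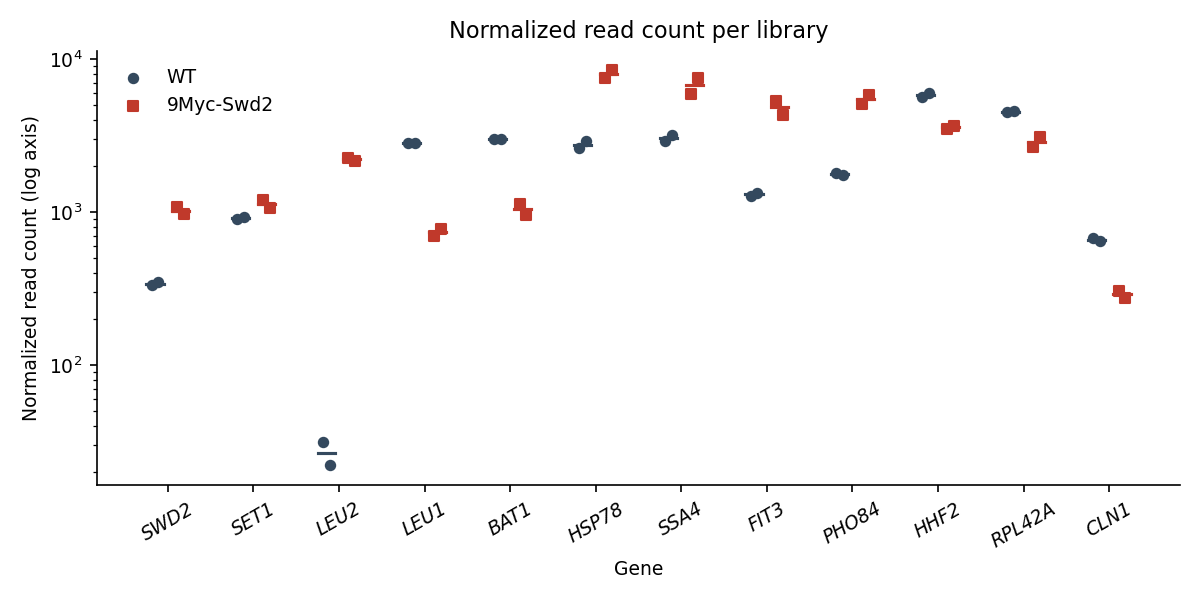
Normalized read count (y axis, log axis) of 12 genes (x axis) in each library; circles are the 2 WT libraries, squares the 2 9Myc-Swd2 libraries, and bars the group means. SWD2 rose from 343 to 1025 and LEU2 from 26.9 to 2219, while LEU1 fell from 2836 to 744.

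Chaperone genes of the kind controlled by the heat shock factor Hsf1 rose together: all 23 members passed the threshold with a rise (23 adjusted over the list alone), with a median log2 fold change of 0.90, and none of them lies on chromosome XI. HSP78, the mitochondrial disaggregase, rose from 2776 ± 206 to 7983 ± 669. HSP42 rose from 4260 ± 88.6 to 10471 ± 856, MDJ1 from 1921 ± 6.94 to 4181 ± 330, and STI1, a co-chaperone of Hsp90, from 3602 ± 46.9 to 7871 ± 519. The camera adjusted p was 2.67e-15 (adjusted p = 0.77 with an estimated correlation). In the general stress response list 35 of 50 genes rose and 5 fell (35 and 5 adjusted over the list alone), with a median of 0.44 and camera adjusted p = 2.59e-08 (adjusted p = 0.77 with an estimated correlation). 33 of the 48 members off chromosome XI rose. DDR2 rose from 364 ± 31.6 to 928 ± 92.3 and HSP26 from 533 ± 18.6 to 1063 ± 3.06; 4 genes, HSP26 and HSP42 among them, belong to both lists. SSA and Hsp90 genes have near-identical paralogs, and their individual counts are uncertain.

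Genes of iron uptake, phosphate starvation and pleiotropic drug resistance were also higher. Of 24 iron uptake genes, 17 rose (17 adjusted over the list alone; 15 of the 22 off chromosome XI), with a median log2 fold change of 0.35 and camera adjusted p = 8.58e-07 (adjusted p = 0.77 with an estimated correlation). FIT2 rose from 689 ± 63.9 to 1949 ± 275, the siderophore transporter gene SIT1 from 592 ± 22.3 to 1185 ± 45.5, and FRE2, a ferric reductase gene on chromosome XI, rose by a log2 fold change of 1.44 ± 0.11. Of 16 phosphate starvation genes, none of them on chromosome XI, 11 rose (11 adjusted over the list alone; median 0.44; camera adjusted p = 6.82e-05; adjusted p = 0.77 with an estimated correlation). The high-affinity phosphate transporter gene PHO84 rose from 1792 ± 43.0 to 5469 ± 488, PHM8 from 353 ± 2.87 to 863 ± 112 and SPL2 from 180 ± 2.85 to 398 ± 6.93. The acid phosphatase gene PHO5, chosen after its value was seen, had a log2 fold change of 0.09 ± 0.10 and did not pass. Of 10 drug resistance genes, none of them on chromosome XI, 8 rose (8 adjusted over the list alone; median 0.49; camera adjusted p = 0.000638; adjusted p = 0.77 with an estimated correlation). TPO1 rose from 582 ± 16.7 to 1046 ± 7.37, the transcription factor gene PDR3 from 1312 ± 5.71 to 2077 ± 10.3 and the efflux pump gene PDR5 from 2900 ± 140 to 4577 ± 38.7.

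Of 16 genes of daughter cell separation and the M/G1 phase, 10 rose (10 rose and 1 fell adjusted over the list alone), 8 of them off chromosome XI, with a median log2 fold change of 0.30 and camera adjusted p = 0.000782 (adjusted p = 0.79 with an estimated correlation). DSE4, a glucanase gene of septum degradation, rose by a log2 fold change of 1.52 ± 0.07 and PRY3 from 1514 ± 90.2 to 2350 ± 206, while PIR1 and ASH1, which also rose, lie on chromosome XI. In the list of the TCA cycle and respiratory chain 17 of 47 genes rose and 4 fell (17 and 4 adjusted over the list alone), with a median of 0.12 and camera adjusted p = 0.00547 (adjusted p = 0.77 with an estimated correlation). Its 4 members with the smallest p, SDH1, ATP7, SDH3 and MDH1, are its 4 members on chromosome XI, with log2 fold changes of 0.93 to 1.21; off this chromosome 13 of 43 rose, and the list still passed without chromosome XI genes (camera adjusted p = 0.011).

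Genes of the translation machinery and the histones were lower. Of 137 ribosomal protein genes, 110 fell and 7 rose (114 and 8 adjusted over the list alone), with a median log2 fold change of -0.35 and camera adjusted p = 3.38e-14 (adjusted p = 0.79 with an estimated correlation). RPL42A fell from 4561 ± 43.7 to 2872 ± 309 and RPL8B from 5749 ± 161 to 3865 ± 224. All 5 members on chromosome XI rose, among them RPL17A, from 6354 ± 360 to 9887 ± 10.5; RPS14B, on chromosome X, rose from 1095 ± 31.6 to 1738 ± 77.1. Many ribosomal protein genes have a near-identical paralog, and reads may be shared within such pairs. Of 82 ribosome biogenesis genes, 38 fell and 12 rose (39 and 13 adjusted over the list alone), with a median of -0.13 and camera adjusted p = 0.00277 (adjusted p = 0.84 with an estimated correlation; 0.080 with the preset correlation without 9Myc-Swd2 replicate 2). All 5 of its chromosome XI members rose, among them RRN3, a factor of RNA polymerase I, from 596 ± 8.90 to 1605 ± 126, while RRP8, an rRNA methyltransferase gene on chromosome IV, fell from 1948 ± 49.9 to 1176 ± 23.9. All 8 core histone genes, none of them on chromosome XI, fell (8 adjusted over the list alone), with a median of -0.47 and camera adjusted p = 6.82e-05 (adjusted p = 0.77 with an estimated correlation). HHF2 fell from 5852 ± 226 to 3595 ± 97.1, HHT2 from 6187 ± 337 to 3859 ± 17.6 and HTB2 from 4722 ± 141 to 3274 ± 103; copies of each histone gene are near-identical.

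**Figure D4:**
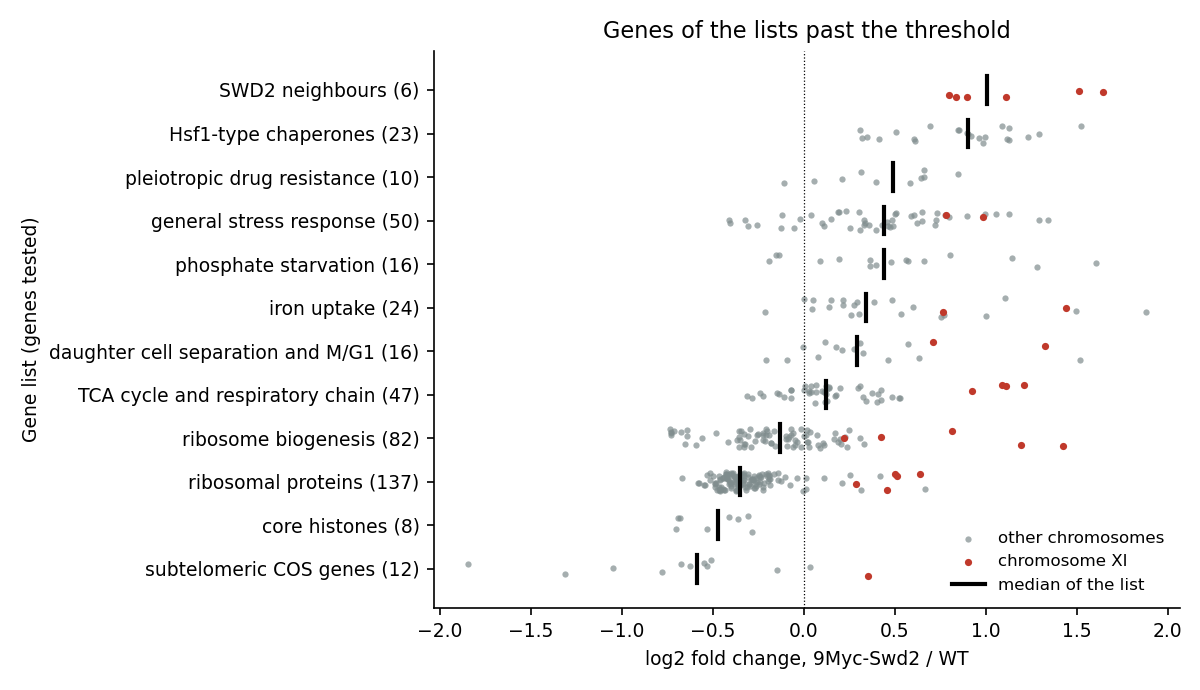
Log2 fold change of 9Myc-Swd2 over WT (x axis) of every tested gene of the 12 gene lists past the camera threshold (y axis, number of genes tested in brackets); red points are genes on chromosome XI, grey points genes elsewhere, and black bars the medians. The medians run from 1.00 for the neighbours of SWD2 and 0.90 for the chaperones to -0.35 for ribosomal proteins, -0.47 for core histones and -0.59 for COS genes.

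Of 12 genes named COS, 8 fell and 1 rose (8 and 1 adjusted over the list alone), with a median log2 fold change of -0.59 and camera adjusted p = 0.00277 (adjusted p = 0.79 with an estimated correlation). COS2 fell from 660 ± 43.1 to 319 ± 14.3 and COS3 from 235 ± 25.5 to 95.3 ± 24.9, while COS9, the member that rose, lies on chromosome XI. The COS genes are a subtelomeric family with near-identical copies, so single values are uncertain; COS111, which shares only the name, was at 664 ± 26.8 and 682 ± 32.1 and did not pass. COS9 and COS111 were chosen after their values were seen. The wider list of genes within 20 kb of a chromosome end had 22 of 229 genes higher and 42 lower (21 and 37 adjusted over the list alone; camera adjusted p = 0.13). Among 8 Y' helicase genes YRF1-7 fell (1 adjusted over the list alone; camera adjusted p = 0.44). Of the 24 PAU genes 0 passed the limma-trend threshold, with 2 at an unadjusted p under 0.05 and 0 by edgeR or DESeq2.

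The partners of Swd2 did not move one way. Of 8 COMPASS subunit genes, SWD2 and SET1 rose and SDC1 and SPP1 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.99). SET1, the methyltransferase gene, rose from 919 ± 13.2 to 1134 ± 94.0, with a log2 fold change of 0.30 ± 0.08 that did not pass with limma without a trend (adjusted p = 0.067). SDC1 fell from 406 ± 3.71 to 305 ± 31.0 and SPP1 from 548 ± 25.7 to 438 ± 10.7; SPP1 did not pass without WT replicate 2 (limma adjusted p = 0.11). Of 15 genes for CPF and APT subunits, 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.076, and 0.022 without 9Myc-Swd2 replicate 2). The adjusted p was 0.55 without chromosome XI genes, which leaves 12 members, and 0.79 with an estimated correlation. SWD2, the poly(A) polymerase gene PAP1 (865 ± 1.47 to 1868 ± 91.0) and MPE1 (603 ± 32.6 to 1121 ± 143) lie on chromosome XI. Off it, PTA1 and REF2 rose by log2 fold changes of 0.39 and 0.43, and the phosphatase gene GLC7 and SYC1 had log2 fold changes of -0.34 and -0.59 and fell. Of 8 genes for subunits of CF I and the Nrd1 complex, HRP1, SEN1, NRD1 and PCF11 rose by 0.47, 0.31, 0.22 and 0.25 (4 adjusted over the list alone; camera adjusted p = 0.21). Of 11 genes for H2B ubiquitination, the Paf1 complex and histone methylation, LGE1 rose and LEO1, PAF1 and RTF1 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.16). Of 32 protein-coding genes next downstream of snoRNA genes, 11 rose and 12 fell (13 and 12 adjusted over the list alone). The camera adjusted p of this list was 0.69. Its 3 members on chromosome XI, RGT1, UBA1 and SFT1, rose. Of the 29 members off this chromosome, 8 rose and 12 fell. The smallest p among these was that of YDR042C, named above among the largest rises, which rose from 62.0 ± 3.78 to 191 ± 9.41.

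Marker genes of both mating types were read in both groups. The alpha-specific genes were mostly the higher ones, and the ranges of the group means overlapped only through the a-specific gene STE6. The values are not scaled to gene length, so this ranking of different genes is only approximate. The 8 alpha-specific genes had means from 163 (MATALPHA1) to 6659.7 normalized counts (MF(ALPHA)1) in WT and from 175 (HMLALPHA1) to 5839.6 (MF(ALPHA)1) in 9Myc-Swd2. The 7 a-specific genes had means from 16.8 (MFA1) to 476 (STE6) in WT and from 31.0 (MFA2) to 780 (STE6) in 9Myc-Swd2. Those other than STE6 reached at most 161 (BAR1) in WT and 166 (STE2) in 9Myc-Swd2. MATALPHA1, HMLALPHA1, MF(ALPHA)1, MFA2 and BAR1, which mark the ends of these ranges, were chosen after their values were seen, and none of them passed the threshold. The genes at MAT and HML have near-identical copies, so their single values are uncertain. MATALPHA2 (1905 ± 107 to 1498 ± 79.6) and HMLALPHA2 (1852 ± 143 to 1498 ± 24.0) both fell. They are counted separately in the alpha-specific list, though their falls may be 1 shared signal. In the a-specific list 3 of 7 genes rose (3 adjusted over the list alone; camera adjusted p = 0.14), namely STE6, which lies on chromosome XI, MFA1 (16.8 ± 3.13 to 51.3 ± 5.60) and AGA2 (16.8 ± 2.31 to 42.7 ± 12.3). In the alpha-specific list 4 of 8 fell (5 adjusted over the list alone; camera adjusted p = 0.076, 0.048 without WT replicate 1, and adjusted p = 0.79 with an estimated correlation), among them MF(ALPHA)2, from 651 ± 15.1 to 404 ± 9.62. Of 9 haploid-specific genes 4 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.81). Of 58 meiosis and sporulation genes 6 rose and 9 fell (6 and 8 adjusted over the list alone; camera adjusted p = 0.69). Among 8 selectable marker genes, LEU2, CAN1 and HIS3 rose and ADE2, MET17, TRP1 and URA3 fell (3 and 4 adjusted over the list alone; camera adjusted p = 0.96). URA3 was low in all libraries, at 29.3 ± 2.93 in WT and 14.9 ± 3.10 in 9Myc-Swd2, and LYS2, chosen after its values were seen, was at 5.75 and 3.05 and did not pass. Of 8 mitochondrially encoded genes in the list fixed beforehand 5 fell (5 adjusted over the list alone; camera adjusted p = 0.076). In the comparison of chromosomes, 11 of the 26 tested genes of the mitochondrial genome fell and 15 did not pass. That set passed the camera test (adjusted p = 0.00348; adjusted p = 0.50 with an estimated correlation), but not without 9Myc-Swd2 replicate 1 (adjusted p = 0.19) or over its 12 genes of at least 5 CPM (adjusted p = 0.11). Reads of the mitochondrial genome were 0.0331% ± 0.000364 of the WT libraries and 0.0233% ± 0.00211 of the 9Myc-Swd2 libraries.

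Cell cycle and metabolic lists other than those above did not pass the camera test. Of 24 G1/S genes 9 fell, among them the G1 cyclin gene CLN1 (log2 fold change -1.18 ± 0.09) and MCD1, and 3 rose (10 and 3 adjusted over the list alone; camera adjusted p = 0.062). Without chromosome XI genes this list passed (camera adjusted p = 0.010), as it did without WT replicate 2 (0.044) or without 9Myc-Swd2 replicate 1 (0.015). It did not pass without 9Myc-Swd2 replicate 2 (0.17) or, over all libraries, with an estimated correlation (adjusted p = 0.79). The G2/M list had 4 of 14 genes higher and 3 lower (4 and 3 adjusted over the list alone). Of 37 amino acid biosynthesis genes 11 rose and 7 fell (12 and 8 adjusted over the list alone; camera adjusted p = 0.96), with ILV3 falling from 3622 ± 0.372 to 1811 ± 57.6 and SNZ1 rising by a log2 fold change of 1.20. Of 14 hexose transporter and sensor genes 4 rose, HXT1 from 1074 ± 18.3 to 2605 ± 36.8, and 4 fell (4 and 4 adjusted over the list alone). Of 17 genes of glycolysis and ethanol formation 4 rose and 6 fell (5 and 6 adjusted over the list alone), TDH2 from 13417 ± 619 to 6735 ± 519; the TDH genes are closely similar paralogs, and their reads may be shared. The proteasome list had 7 of 32 genes higher and 4 lower (5 and 2 adjusted over the list alone). The cell wall list had 13 of 35 higher and 9 lower (14 and 9), with 6 members on chromosome XI. The unfolded protein response list had 6 of 14 higher and 2 lower (6 and 2), among them KAR2, the chaperone gene of the endoplasmic reticulum, at a log2 fold change of 0.85. Of 24 sulfur and methionine genes 6 rose and 8 fell (6 and 8), and of 24 ergosterol and mevalonate genes 7 rose and 8 fell (8 and 8). Of 23 genes under nitrogen catabolite repression 9 rose and 2 fell (9 and 2), of 34 glucose-repressed genes 9 rose and 4 fell (9 and 4), and of 19 pheromone response genes 5 rose and 4 fell (6 and 8), with the counts adjusted over the list alone in brackets. The lists of zinc response, thiamine biosynthesis and DNA damage had 3 of 9, 2 of 18 and 2 of 15 genes higher and as many lower in each (3 and 4, 2 and 2, and 1 and 1 adjusted over the list alone), and in the galactose list GAL80 fell and 8 genes did not pass (1 lower adjusted over the list alone). The median and the mean log2 fold change differed in sign in the lists of COMPASS subunits, amino acid biosynthesis, ergosterol and mevalonate, zinc response, glycolysis and ethanol, glucose-repressed genes, galactose, hexose transporters, pheromone response, PAU genes and selectable markers, none of which passed the camera test at the preset correlation.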

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

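The tests on recovered reads, the scalings to total counts and without chromosome XI, the tests without chromosome XI genes and every alternative value of the chromosome XI median were chosen after the data were seen. Relative to the 1448 higher and 1393 lower genes, the number of higher genes was 849 in the authors' deposited table at an adjusted p under 0.01 and 182 at a log2 fold change of at least 1. The number of lower genes was 668 and 52 in these settings. The first differs in both test and threshold (1094 higher and 955 lower in the authors' deposited table at 0.05), and the second adds a condition to the same calls. Without a trend limma gave 882 lower genes, and the cause was not tested. With 1 library left out, higher genes numbered 972 to 1596 and lower genes 780 to 1440, the lowest of both without WT replicate 2; the lone library was then assumed to vary like the other group. Between 1187 and 1619 genes were higher, and between 1269 and 1728 lower, under quantile normalization, no filter, a filter at 5 CPM, a pseudocount of 0.1, edgeR, the replicate block and the scalings; the authors' deposited table at 0.05 and DESeq2 on the recovered reads gave 1094 and 1101 higher and 955 and 962 lower, and 1123 rose and 1370 fell without chromosome XI genes. The replicate block gave 1619 higher and 1566 lower genes and 10 higher and 4 lower lists, with no list call lost. Calls were gained by the CPF and APT subunits (camera adjusted p = 0.032 against 0.076) and the selectable markers (0.042 against 0.96). The camera direction of the selectable markers turned from down in the main test to up. LEU2, with a log2 fold change of 6.34, is by far their largest change. Over 5776 genes the deviations of same-numbered libraries correlated at 0.18, which with 2 pairs does not show that the numbers pair the samples. The 8 higher and 4 lower gene lists became 0 and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. That form of camera rests on 2 residual degrees of freedom, and chromosome XI did not pass it either (adjusted p = 0.20). For iron uptake the estimated correlation was -0.037, below the preset 0.01, yet the unadjusted camera p rose from 9.98e-08 to 0.027. These lost calls therefore do not argue against the lists. With fry 6 lists were higher and 0 lower, and 7 lists had an unadjusted p under 0.05 with a fall. Fry does not compare a list with other genes, and why it made fewer calls was not tested. With 1 library left out, 8 to 9 lists were higher and 3 to 5 lower. SWD2 kept its rise past the threshold in every alternative that tested it (log2 fold change 1.5 to 1.65). The chromosome XI median was 0.85 to 0.93 in the alternatives that gave one; the tests without its genes, the other thresholds and the other list tests gave none. Of 84 named genes, 1322 values were computed under the alternatives: 1311 kept direction and side of the threshold, 11 values of 5 genes lost the threshold and 0 reversed. These genes were mostly named for large changes or small p-values in the same libraries, so this count does not describe the calls as a whole. With 2 libraries per group and 7849193 to 8388090 reads each, the simulated recovery of 1.5-fold changes by limma-trend was 93%. The simulated changes lay only in genes of at least 5 CPM and gave 198 calls, far fewer than the data. Recovery at lower values was not simulated, and smaller changes are less surely detected. The simulated spread was equal in both groups and had no variation of single genes about its trend. In the data the chi-square per gene was 3.42 for the WT pair and 8.84 for the 9Myc-Swd2 pair. The simulated recovery and false calls may therefore be optimistic.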

Other observations

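The lists, chromosome comparisons and tests in this part were chosen after the values were seen, except the corrections for GC content and gene length, the test on LEU4, ILV2 and ILV5 and the question of dosage against tag, which were set before their results were looked at; the recount of that LEU4, ILV2 and ILV5 test under other settings was added afterwards.

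Of 6 genes of the synthesis of NAD from tryptophan, 4 fell by similar amounts. BNA1 fell from 1145 ± 50.1 to 465 ± 49.8 normalized counts, and BNA5, BNA6 and BNA7 had log2 fold changes of -1.52, -1.35 and -1.32. BNA2, the dioxygenase gene of the first step, rose from 158 ± 17.9 to 261 ± 3.27, and BNA4 was at 323 ± 0.992 and 343 ± 0.962 and did not pass. As a list they had a camera adjusted p of 0.00247 among 3 lists picked in this way (adjusted p = 0.23 with an estimated correlation).

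The 6 reading frames annotated within the ribosomal DNA repeat, TAR1 among them, all rose, with log2 fold changes from 0.87 to 1.45 (camera adjusted p = 0.000216; adjusted p = 0.23 with an estimated correlation). Their reads made up 2.31% ± 0.105 of the WT libraries and 4.51% ± 0.829 of the 9Myc-Swd2 libraries (SD, n = 2), with 3.92% in 9Myc-Swd2 1 and 5.10% in 9Myc-Swd2 2. The repeat is present in many near-identical copies and the strand used in counting is not given, so that these reads cannot be assigned to the frames themselves.

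Genes of chromosome XI were 1.87-fold higher in the median. A trend with GC content and gene length is argued against, since the median was 0.93 after its removal (310 of 319 genes with values). An effect limited to the surroundings of the tagged SWD2 gene is also argued against, since the 108 genes more than 200 kb from it had a median of 0.97. As a hypothesis, the 9Myc-Swd2 cells may carry an extra copy of the whole chromosome. The lowest of the 12 window medians was 0.82, but the bounds for these medians were set after they had been seen, so that they do not count for this hypothesis, which stays open. The labels call the strains isogenic and no DNA was measured, and whether a copy present in only part of the cells or a dampened response to dosage keeps the median below 2-fold was not tested.

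LEU2 rose 80.7-fold. Of 8 targets of the leucine pathway activator Leu3, 5 fell and MAE1 rose (6 and 1 adjusted over the list alone). As a list they had a camera adjusted p of 0.00032 (adjusted p = 0.23 with an estimated correlation). LEU1, BAT1 and GDH1 had log2 fold changes of -1.93, -1.53 and -1.14, and ILV5 and OAC1 also fell. OAC1 and MAE1 lie on chromosome XI, where genes of at least 5 CPM had a median of 0.90. MAE1, at 0.28 ± 0.08 (SE), lay below that median. Of the 6 targets off this chromosome, 4 fell and 0 rose. A general fall of amino acid biosynthesis genes is argued against, since the 33 listed genes that are not Leu3 targets had a median of 0.0049, with 11 higher and 5 lower. As a hypothesis, leucine made with LEU2 may repress the Leu3 targets, which predicted falls past the threshold in at least 2 of LEU4, ILV2 and ILV5; 1 of the 3 passed, as ILV5 had -0.33 ± 0.07, LEU4 -0.17 ± 0.07 and ILV2 -0.14 ± 0.07 (SE). The prediction was thus missed as written. Under 5 of 17 other settings, which reuse the same 4 libraries, 2 or 3 of these genes passed with a fall. Among these settings were quantile normalization (2) and scaling to total counts (3). In them the median over all genes tested was -0.029 and -0.057, against 0.0011 in the main test. Adjustment over the list alone (2) used a list picked from these data. These counts do not offset the miss, and this test neither bears out nor excludes the hypothesis. What the strains carry at LEU2 is not given in the labels. A genotype difference at LEU2 and a change in its expression can therefore not be told apart. In WT, LEU2 was at 26.9 ± 6.37, close to URA3 (29.3 ± 2.93) and above LYS2 (5.75). HIS3, TRP1, CAN1, MET17 and ADE2 lay between 590 and 3368 in WT. The values are not scaled to gene length, so different genes are compared only approximately.

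Chaperone genes rose and ribosomal protein genes fell. A trend with GC content and gene length is argued against as the whole cause: after its removal the chaperone median was 0.85 (0.90 before) and the ribosomal protein median -0.24 (-0.35 before, interquartile range after removal -0.34 to -0.12), so part of the latter goes with that trend. Whether these changes go with the tag, with the raised chromosome XI or with the high LEU2 cannot be told apart. 0 libraries had a raised chromosome XI without the tag, and LEU2 was high in the tagged libraries only. The same limit holds for the other differences between the groups. All of these remain open, as does the growth state of the cultures at harvest, which was not tested.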
